A study of Eleocharis dulcis with 24 samples.

How the data were processed

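RNA from corms of cultivated and wild *Eleocharis dulcis* was sequenced on the DNBSEQ-T7 platform, per the series design, at 4 developmental stages with 3 biological replicates per stage and origin. The authors deposited 1 table of TPM values (transcript abundances scaled to a fixed library total, rounded to 2 decimals) with 1 row per gene and 1 column per library. HISAT2 2.0.4, StringTie 2.1.6 and DESeq2 are named in the submitters' processing notes, without a role or an order. The genome build, the annotation and any filters are not given in the sources used here. Column names held a letter for the origin, a digit for the stage and a replicate number, and each of the 24 columns was matched to its sample by the origin, stage and sample number in its title. No column was left over.

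TPM carries no depth: column totals lay between 999991 and 1000002, so no interval from counts could be given and the precision of a value was taken from the spread of the 3 replicates. TPM is also a share of a fixed total, so a gene that takes a large share lowers all others. For that reason the splits into higher and lower genes by comparison, and the overlap of the changes in both origins, were also computed after median-of-ratios scaling of the TPM values. Of 35975 genes, 3192 were at 0 in every library, and 27050 with a TPM of at least 1 in at least 3 libraries were kept.

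Count models do not apply to TPM, so log2(TPM + 1) values were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend). All 24 libraries entered 1 fit with 8 group means, so that groups shared an estimate of the spread, with no replicate block. Contrasts were each pair of successive stages and maturity against initial within each origin, cultivated against wild at each stage and averaged over stages, and the interaction of origin and stage. F tests covered any stage difference. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold change means at least 1 on the log2(TPM + 1) scale. Shares of TPM and numbers of detected genes were compared between origins with a two-sided permutation test within stages (100000 resamples) and between stages with the exact permutation test, adjusted over 9 tests. Genes near 0 in one origin were those under 0.1 TPM in all 12 of its libraries and at least 1 TPM in all 12 of the other. Values expected by independent lists are the product of both counts divided by the genes tested, or, for peak stages, by the genes that differed between stages in both origins.

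The design, the tests and most alternatives were fixed before the data were examined. Genes named in the text had an adjusted p under 0.05, a mean of at least 10 TPM on the higher side and every library of that side above every library of the other. The 2 largest rises and 2 largest falls by this rule were named for maturity against initial in each origin and for cultivated against wild over stages. The share of TPM taken by novel1867, the highest feature in most libraries, was chosen for description after its values were seen.

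A total of 20 gene lists (hormones, starch, cell wall and others) had been fixed in advance. They were not tested, and no gene set test was run, because no table used here pairs the IDs with gene names.

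The test was tried on simulated data for cultivated maturity against initial with 27050 genes, in which 50 genes were changed at each of 4 sizes. It recovered 80, 88, 98 and 98% of genes changed by 0.5, 1, 2 and 4 (log2), with 15 false calls among 197. All other simulated genes were unchanged and no fixed total was imposed. These rates need not hold in the data, where most genes were called and shares of the total shifted. Alternatives were a pseudocount of 0.1, no filter on low values, a mean TPM of at least 5, median-of-ratios scaling, only the compared groups in the fit, a replicate block, each library left out in turn, and, chosen after seeing the data, removal of the 10 genes with the highest mean TPM.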

Results

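Corms of *Eleocharis dulcis* (Chinese water chestnut, a sedge grown for its edible underground storage stem) were profiled by RNA sequencing in cultivated and in wild plants at 4 stages of development: initial, middle and late swelling, and maturity. Each of the 8 groups held 3 libraries from separate biological samples, which gave 24 libraries in all. The deposited values were TPM (transcript abundances scaled to a fixed library total) for 35975 genes, of which 33415 carried an ID with the prefix EdulChr and 2560 an ID without it. Library totals lay between 999991 and 1000002 TPM, so the sequencing depth behind each value is unknown and no counting interval could be given. A total of 27050 genes reached a TPM of at least 1 in at least 3 libraries and were tested. IDs were not paired with gene names, so genes are given by ID and no function is assigned to them.

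Libraries of one group lay close together and groups lay apart. Spearman correlations across genes ranged from 0.984 to 0.992 within groups and from 0.512 to 0.961 between groups. The first principal component held 56.9% of the variance and the second 21.0%. Cultivated corms at middle, late and maturity formed a tight region that lay far from cultivated corms at the initial stage. Wild corms at the initial and middle stages lay near each other, with late and mature corms progressively farther away.

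**Figure D1:**
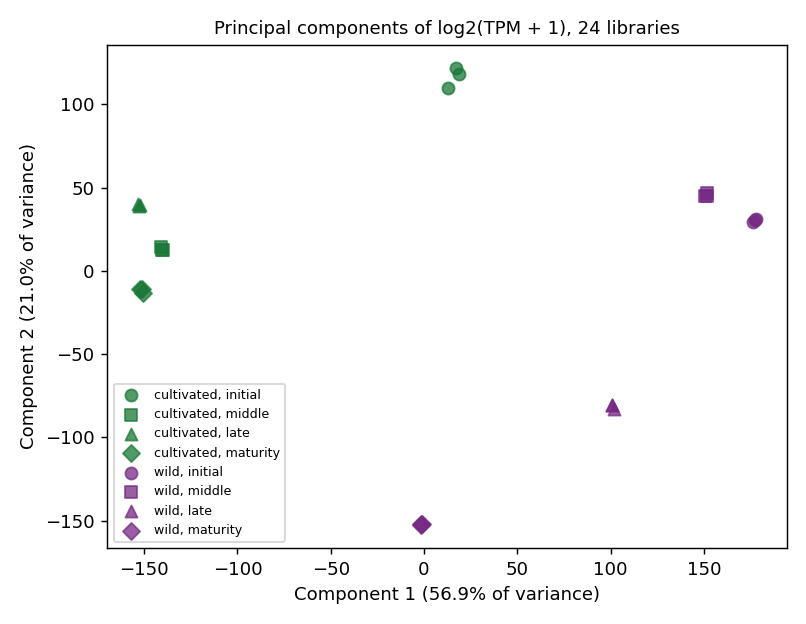
Principal components of log2(TPM + 1) for the 24 libraries, component 1 (56.9% of variance) on the x axis and component 2 (21.0%) on the y axis, both in component score units. Colour marks the origin and shape the stage, and each point is 1 library. Cultivated corms at the initial stage lie apart from the 3 later cultivated stages, and wild corms spread along both components from middle to maturity.

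In cultivated corms, the largest rise from the initial stage to maturity among genes that met the rule for named genes was that of EdulChr3G00014480. This gene went from 14.6 ± 2.78 TPM to 27671 ± 569 TPM (SD, n = 3 each). The log2 change was 10.80 ± 0.26 (SE, limma adjusted p = 4.27e-19). The feature novel1867 rose from 1361 ± 87.2 to 131633 ± 5597 TPM (SD, n = 3), a log2 change of 6.60 ± 0.07 (SE, limma adjusted p = 2.16e-24). EdulChr27G00110080 fell from 3532 ± 218 to 0.103 ± 0.0603 TPM (SD, n = 3), a log2 change of -11.64 ± 0.19 (SE, limma adjusted p = 6.55e-22). EdulChr53G00191470 stood at 1349 to 1539 TPM in the initial libraries and was listed at 0 in all 3 mature libraries. By the middle stage both had fallen: EdulChr27G00110080 had dropped to 7.14 ± 1.84 TPM and EdulChr53G00191470 to 1.26 ± 0.627 TPM (SD, n = 3). EdulChr3G00014480 rose in 2 steps, to 3063 ± 140 TPM by the middle stage and, after a late value of 3235 ± 55.0 TPM, to its mature level (SD, n = 3). Changes are on the log2(TPM + 1) scale, which understates the change of low genes.

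In cultivated corms the step from the initial to the middle stage held the most genes with a change of at least 2-fold. In that step 10800 genes passed limma's test with at least a 2-fold change, 2445 higher and 8355 lower at the middle stage. From middle to late the count was 3414 genes (2400 higher, 1014 lower), and from late to maturity 3346 (584 higher, 2762 lower). These 2 counts were 6088 and 6106 with a pseudocount of 0.1. From initial to maturity it was 11873 genes, 2147 higher and 9726 lower. In the test of any stage difference, 25386 of 27050 genes passed. Mature cultivated libraries correlated slightly more with middle (Spearman 0.957 to 0.961) than with late libraries (0.955 to 0.956). The median TPM over genes was 8.24 ± 0.416, 4.91 ± 0.0569, 6.46 ± 0.0115 and 4.42 ± 0.0513 from initial to maturity (SD, n = 3). Because TPM values share a fixed total, the same fits were made after median-of-ratios scaling. The median log2 change in the 3 steps and from initial to maturity was -0.47, 0.15, -0.31 and -0.61 as deposited. After scaling it was -0.11, -0.01, 0 and -0.12. The splits into higher and lower then became 4145 and 5224, 1039 and 1689, 1236 and 781, and 4305 and 5656, so the prevailing direction of the 2 later steps depended on the scaling. When only the 10 highest genes were removed, an alternative chosen after seeing the data, 66.8% of calls were higher from middle to late and 33.9% from late to maturity, the directions of the values as deposited.

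In wild corms, EdulChr3G00014480 again had the largest rise from initial to maturity by the rule for named genes. It went from 9.58 ± 7.62 to 46596 ± 2144 TPM (SD, n = 3), a log2 change of 12.33 ± 0.26 (SE, limma adjusted p = 3.67e-20). EdulChr37G00143200 rose from 9.93 ± 2.72 to 13701 ± 469 TPM (SD, n = 3), a log2 change of 10.32 ± 0.11 (SE, limma adjusted p = 6.05e-25). novel639 fell from 812 ± 16.7 to 0.47 ± 0.265 TPM (SD, n = 3), a log2 change of -9.13 ± 0.09 (SE, limma adjusted p = 2.18e-25). EdulChr22G00090460 stood at 575 to 658 TPM at the initial stage and was listed at 0 in all 3 mature libraries. In wild corms EdulChr22G00090460 still stood at 613 ± 35.0 TPM at the middle stage and at 29.9 ± 3.26 TPM at the late stage, while novel639 passed through 375 ± 15.8 and 55.7 ± 1.39 TPM (SD, n = 3). In cultivated corms both were near or at 0 from the middle stage on: EdulChr22G00090460 was listed at 0 in every library, and novel639 at 0.1 to 0.31 TPM at the middle stage and 0 thereafter.

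**Figure D2:**
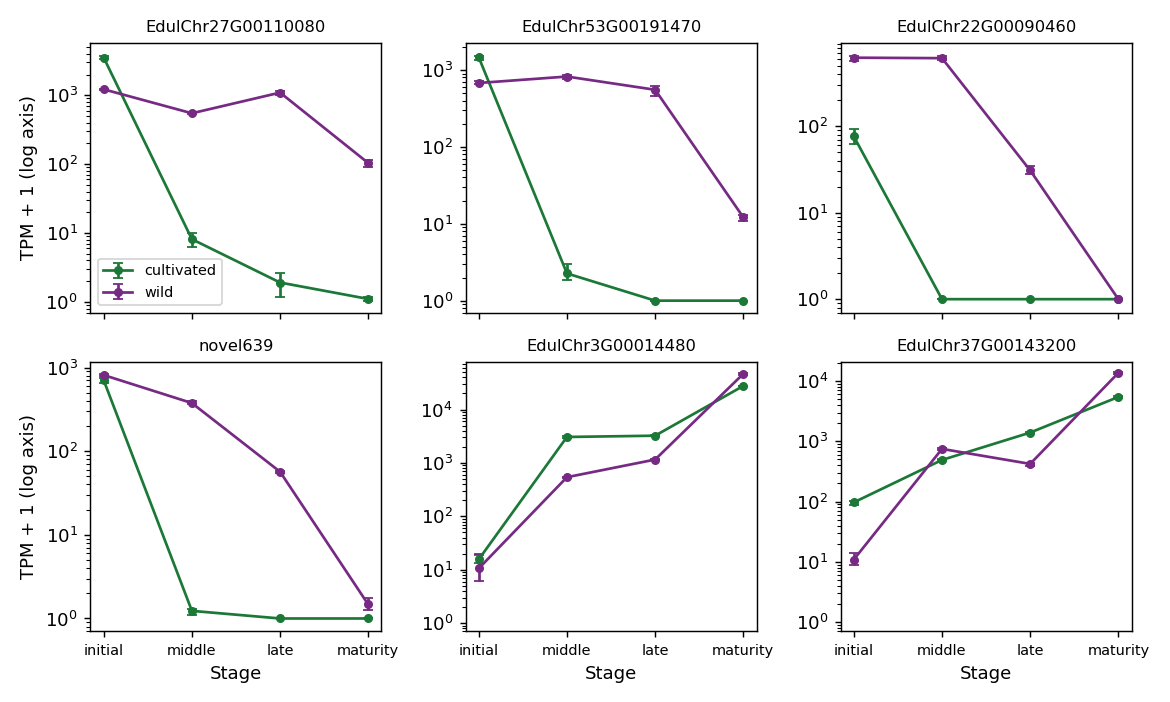
Mean TPM + 1 (log axis) at each stage for 6 of the genes named in the text, with bars from the lowest to the highest of 3 libraries. The 4 genes that fell had means of 0 to 7.14 TPM at the middle stage in cultivated corms (green), whereas in wild corms (purple) they stood at 375 to 821 TPM at that stage.

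From initial to middle, 2752 genes changed at least 2-fold in wild corms (1180 higher, 1572 lower), and 4281 with a pseudocount of 0.1. The 2 later steps held more: 9372 genes from middle to late (2124 higher, 7248 lower) and 8452 from late to maturity (1043 higher, 7409 lower). From initial to maturity 13705 genes changed at least 2-fold, 1160 higher and 12545 lower, and 26060 genes passed the test of any stage difference. The median log2 change in the 3 steps and from initial to maturity was 0.08, -0.53, -0.42 and -0.90 as deposited. After median-of-ratios scaling it was 0.02, -0.03, -0.12 and -0.14. The scaled splits were 898 and 1623, 3925 and 3006, 2734 and 5508, and 3807 and 6304, so the direction of the step from middle to late depended on the scaling among genes with 2-fold changes. Without the 10 highest genes 24.8% of all calls in that step were higher, against 22.5% as deposited and 48.4% after scaling. The same removal moved the share more from late to maturity, to 40.1% against 22.4% as deposited. From initial to maturity it was 27.9%, against 12.9% as deposited. The ratio of counts from initial to middle, cultivated over wild, was 3.92 as deposited, 3.72 after scaling and 3.23 with a pseudocount of 0.1.

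**Figure D3:**
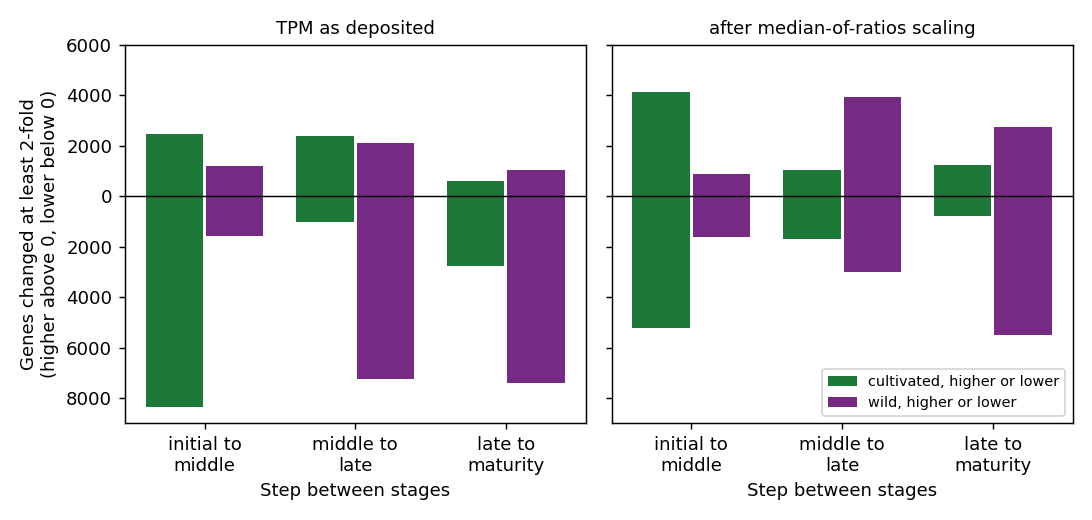
Number of genes (y axis) with an adjusted p under 0.05 and at least a 2-fold change at each step between stages (x axis), higher above 0 and lower below 0, for cultivated (green) and wild (purple) corms. The left panel uses TPM as deposited and the right panel TPM after median-of-ratios scaling. The first step holds most changes in cultivated corms (10800 and 9369 genes in the left and right panels) and the fewest in wild corms (2752 and 2521).

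The next comparison asked which genes differed between cultivated and wild corms. Its p-values rest on the spread of 3 libraries per group and do not measure variation among cultivated or among wild plants at large. The sample titles give no plant line, growing site or batch, so these cannot be told apart from origin. Neither can mapping to a reference genome of unstated origin. Averaged over the 4 stages, and among genes that met the rule for named genes, EdulChr2G00006240 was the gene most in excess in cultivated corms. It had a log2 difference of 8.45 ± 0.31 (SE, limma adjusted p = 1.96e-16). It rose from 331 ± 19.1 TPM at the initial stage to 21143 ± 1110 TPM at maturity in cultivated corms, against 3.14 ± 5.43 and 86.9 ± 3.21 TPM in wild corms (SD, n = 3). EdulChr19G00080780 followed with a log2 difference of 7.79 ± 0.04 (SE, limma adjusted p = 6.38e-30), and was highest in cultivated late corms at 2109 ± 29.3 TPM against 0.793 ± 0.31 TPM in wild late corms (SD, n = 3). EdulChr66G00225550 was lower in cultivated corms by a log2 difference of -9.19 ± 0.08 (SE, limma adjusted p = 7.20e-27), with 3731 ± 61.5 TPM in wild corms at the middle stage and 0 to 0.38 TPM in the cultivated ones. EdulChr25G00102080 was lower by -9.07 ± 0.02 (SE, limma adjusted p = 8.36e-36), with 2063 ± 62.4 TPM in wild late corms and 0.09 ± 0.0361 TPM in cultivated late corms (SD, n = 3).

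Differences of at least 2-fold between the origins numbered 11159 genes at the initial stage, 14901 at middle, 14655 at late and 10794 at maturity. Averaged over stages there were 11431, of which 5760 were higher and 5671 lower in cultivated corms. After scaling the split was 4301 and 6939, and the median log2 difference over stages was -0.21, against 0.01 as deposited. Of all calls, 54.3% were higher in cultivated corms at the initial stage, 35.3% at middle, 57.5% at late and 62.8% at maturity. With scaling these shares were 47.0, 42.2, 43.3 and 45.3%, and without the 10 highest genes 55.5, 36.5, 55.7 and 56.1%, so the prevailing direction at initial, late and maturity turned over with the scaling and not with the removal of these genes. A difference of at least 2-fold in the same direction at all 4 stages was seen in 2111 genes higher and 1325 lower in cultivated corms, and in 1375 and 2193 after scaling. A further 1906 genes had 2-fold differences whose direction changed between stages.

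Corms of both origins were then compared in how they changed from initial to maturity. Across genes, which are not independent replicates, the log2 changes of cultivated and wild corms had a Pearson r of 0.494 and a Spearman rho of 0.426. The 2 changes share no library. Of 20711 genes called in both, 78.3% moved in the same direction. Most calls were lower at maturity in both origins, which by itself gives many matches: 14774 genes were lower in both (13484 by independent lists) and 1439 higher in both (637 by independent lists). With at least 2-fold changes, 422 genes were higher at maturity in both (92.1 by independent lists), 6350 lower in both (4511 by independent lists) and 503 went opposite ways (1413 by independent lists). These splits depended on the scaling. After median-of-ratios scaling 71.9% of 18663 genes called in both moved in the same direction, 5516 higher in both (3485 by independent lists) and 7899 lower in both (5806 by independent lists). The scaled 2-fold numbers were 1392 higher in both (606 by independent lists), 2963 lower in both (1318) and 505 opposite (1799). The change from initial to maturity, in size or direction, differed between origins for 21469 genes, and the stage profile for 26483. EdulChr37G00143200 rose in cultivated corms from 96.1 ± 8.28 to 5456 ± 280 TPM (SD, n = 3), a smaller rise than in wild corms (difference in log2 change, cultivated minus wild, -4.50 ± 0.15, SE, limma adjusted p = 2.43e-16).

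The feature novel1867 was the highest in 18 of 24 libraries. It took 0.136, 3.66, 1.17 and 13.2% of all TPM in cultivated corms from initial to maturity, and 2.55, 7.64, 11.6 and 24.7% in wild corms. It fell by 1.65 (log2) from middle to late in cultivated corms (SE 0.07, limma adjusted p = 8.17e-14), the step in which it rose by 0.60 in wild corms (SE 0.07, limma adjusted p = 1.93e-07). The 10 highest genes of each library together held 15.5 ± 2.72, 16.3 ± 0.138, 12.7 ± 0.155 and 30.1 ± 0.584% of TPM in cultivated corms, and 7.38 ± 0.235, 13.6 ± 0.518, 19.3 ± 1.10 and 42.2 ± 0.173% in wild corms (SD, n = 3). Mature libraries lay above initial libraries in both origins, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (two-sided, adjusted p = 0.113 over 9 tests). The share was higher in cultivated corms at the initial and middle stages and higher in wild corms at the late stage and maturity, so the mean difference over stages, -1.94 percentage points (two-sided permutation test within stages, p = 0.301), averages opposite signs and does not show that the origins were alike. With the 100 highest genes the sign turned, to 2.09 points (permutation p = 0.313).

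**Figure D4:**
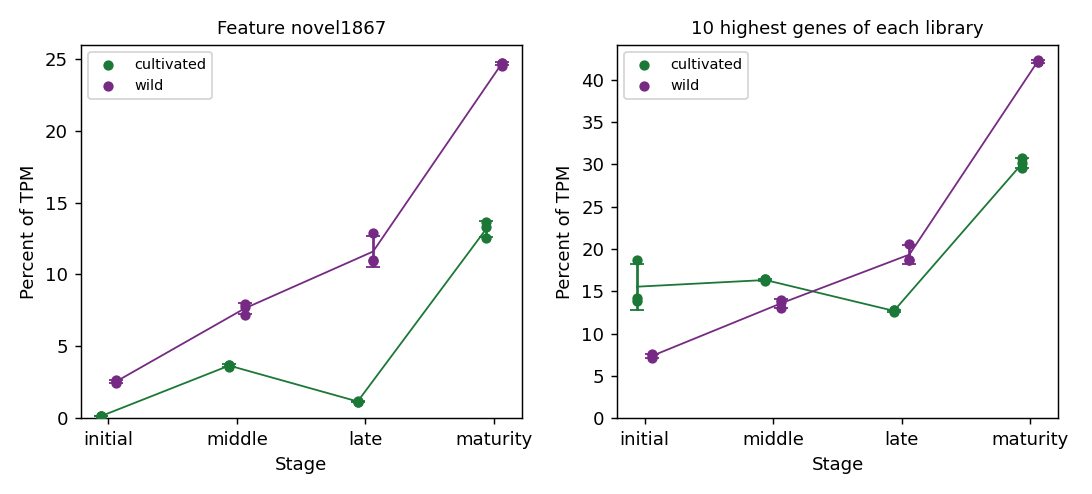
Percent of all TPM (y axis) taken by the feature novel1867 (left panel) and by the 10 highest genes of each library (right panel) at each stage (x axis). Points are single libraries, lines join the means of 3 libraries and bars show the SD. At maturity novel1867 took 13.2% in cultivated and 24.7% in wild corms.

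Fewer genes reached a TPM of at least 1 in mature than in initial corms. A fixed TPM minimum is harder to reach where a few genes hold much of the total. The 10 highest genes held 42.2% of TPM in mature and 7.38% in initial wild corms, and 30.1% and 15.5% in cultivated corms. How far this lowered the number of genes was not tested, and depth is unknown. The number went from 23843 ± 125 at the initial stage through 19706 ± 39.7 and 20526 ± 28.0 to 19263 ± 22.3 at maturity in cultivated corms, and from 23721 ± 77.8 through 24299 ± 40.8 and 21318 ± 91.7 to 17827 ± 10.7 in wild corms (SD, n = 3). The exact permutation p for maturity against initial was 0.1 in each origin, the smallest possible. Over stages the mean difference between origins was -957 genes, which did not pass the permutation test (two-sided, p = 0.0843, adjusted p = 0.113). It too averages opposite signs, since cultivated corms had fewer genes at middle and late and more at initial and maturity. This depended on the detection minimum: at a TPM of at least 0.1 cultivated corms had fewer genes at every stage (mean difference -2072, permutation p = 2e-05). At 5 the mean difference was 624 (permutation p = 0.206).

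A set of 36 genes stood at 1 TPM or more in all 12 cultivated libraries and under 0.1 TPM in all 12 wild libraries, and 21 genes showed the opposite pattern. With limits of 2 and 0.5 TPM these numbers were 59 and 49. The highest mean among them was 73.9 TPM on the cultivated and 118 TPM on the wild side, with medians of 6.77 and 7.90 TPM. IDs without the EdulChr prefix made up 18 of the 36 and 12 of the 21, against 2415 of the 27050 genes tested.

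Stages of the origins were matched by the Spearman correlation across genes of group means centred within each origin. Cultivated initial corms were closest to wild initial corms (0.48), cultivated middle to wild late (0.37), cultivated late to wild maturity (0.34) and cultivated maturity to wild maturity (0.23, against 0.20 for wild late). Single library pairs for the last ranged from 0.211 to 0.233, and those with wild late from 0.171 to 0.200. Without centring, the closest wild stage of cultivated initial corms was middle (0.772) and that of cultivated middle corms was maturity (0.762).

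**Figure D5:**
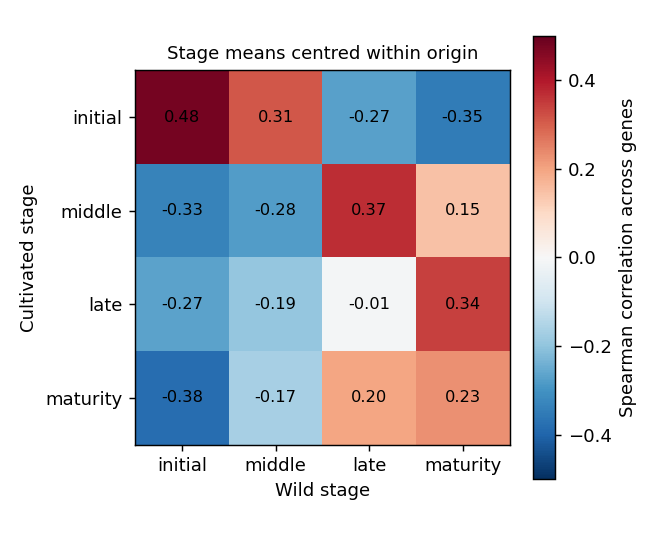
Spearman correlation across genes between the cultivated stages (rows) and wild stages (columns), from group means centred within origin, with the value written in each cell and colour from blue (negative) to red (positive). The highest value in each row is 0.48, 0.37, 0.34 and 0.23 from initial to maturity.

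Among the genes that differed between stages, 55.0% were highest at the initial stage in cultivated corms, 11.1% at middle, 28.0% at late and 5.84% at maturity. In wild corms 33.1% were highest at initial, 43.1% at middle, 16.5% at late and 7.30% at maturity. After scaling the cultivated shares were 45.2, 19.3, 16.5 and 19.0%, and the wild shares 23.9, 22.6, 26.8 and 26.7%. In wild corms the middle stage thus no longer held the most genes, and late and maturity were nearly equal (6980 and 6968 genes). Of 24580 genes that differed between stages in both origins, 33.7% were highest at the same stage, against 28.0% for independent lists. This share is from TPM as deposited and was not computed after scaling.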

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

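Of the tests given here, the removal of the 10 and of the 100 highest genes, the exchanged stage labels, those on IDs without the EdulChr prefix, and the use of the planned scaling on the ratio of first-step counts were chosen after the results were seen.

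The change from initial to maturity differed between the origins for 21469 genes and the stage profile for 26483 (limma interaction tests). Among the named genes the cultivated minus wild difference in log2 change was -1.52 for EdulChr3G00014480 (-1.525 before rounding), 3.32 for novel1867, -8.08 for EdulChr27G00110080, -4.50 for EdulChr37G00143200 (-4.505 before rounding) and -0.33 for novel639. That of EdulChr27G00110080, at 0.103 TPM in mature cultivated corms, depends on the pseudocount. The fitted differences of -4.71 for EdulChr53G00191470 and 3.04 for EdulChr22G00090460 (3.045 before rounding) rest on groups listed at 0, as does that of novel639, and move with the pseudocount. The sign of the difference for EdulChr22G00090460 reflects its lower start in cultivated corms, 75.3 TPM against 621 TPM.

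The median gene fell from initial to maturity, with a log2 change of -0.61 in cultivated and -0.90 in wild corms. A few dominant genes could produce this. Without the 10 highest genes the medians were -0.36 and -0.47, and without the 100 highest -0.34 and -0.35, so such genes account for part of the fall and not the whole. Genes at a mean TPM of at least 20 over the initial and maturity libraries had medians of -0.46 and -1.09. The fall was thus not confined to weakly detected genes. That test kept the highest genes, whose rising share lowers strong and weak genes alike. It therefore cannot weigh loss of weakly detected genes as a cause apart from that share. Each of the medians given so far stayed below -0.1 with each library left out. Median-of-ratios scaling left medians of -0.12 and -0.14, but it is built to bring typical genes near 0 and so decides nothing, and a real change of the corm with stage remains open and untested.

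The largest number of 2-fold changes came from initial to middle in cultivated corms and after the middle stage in wild corms. The ratio of the first-step counts was 3.92 as deposited, 3.72 after scaling, 3.23 with a pseudocount of 0.1 and 3.77 among genes at a mean TPM of at least 5, which argues against scaling and against weak genes as its cause. Exchanging the cultivated middle and late labels left it at 3.54 (3.545 before rounding; 9755 against 2752 genes), so such a swap could not account for the pattern. Whether these labels are exchanged stays open: initial libraries correlated more with middle (0.791 to 0.795) than with late libraries (0.757 to 0.760), but mature libraries also correlated more with middle (0.957 to 0.961) than with late (0.955 to 0.956), and other measures, given among the other observations, go both ways. How stages were assigned in each origin, and a true difference in timing, stay open and untested.

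Features whose IDs lack the EdulChr prefix took less of the TPM in cultivated corms from middle to maturity but more at the initial stage, with a mean difference of -6.77 percentage points over stages (permutation p = 0.00164, adjusted p = 0.0148 over 9 tests). Both this mean and the one without novel1867, -0.307 points (permutation p = 0.754), hide opposite stages: the shares in cultivated and wild corms were 11.9 and 8.37% at the initial stage and 17.2 and 30.5% at maturity with it, and 11.7 and 5.97%, then 4.60 and 7.82%, without it, so the mean without it decides nothing. From middle to maturity the difference was -10.2 points with novel1867 and -2.34 points without it (-2.336 before rounding; exact permutation p = 0.00025 for both, the smallest possible), which argues against that feature as the whole cause there, though it holds most of the difference. Shares without novel1867 are of the TPM that remains, so the -10.2 and -2.34 points are on unlike totals. The origin of the reference genome is not given in the sources used here, and a reference closer to one origin remains an open, untested explanation.

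Other splits of the libraries were counted for each number of called genes. For pairs of groups there are 10 splits, too few for a share under 0.05. The real counts were 22746, 17370, 18097 and 23109 in cultivated corms (successive steps, then maturity against initial), 17752, 23082, 20885 and 23893 in wild corms, and 23332, 24275, 23916 and 21096 between origins from initial to maturity. The highest other split gave 35 genes in the first of these and 5 or fewer in the others. For the remaining limma tests only the real split, 1 of 100 drawn, gave as many genes. Splits that mix groups are noisier, since libraries of one group resembled each other more than those of any other group. The counts therefore show that libraries of a group belong together, and do not tell stage or origin from a batch shared by a group. Real and highest other counts were 25386 and 21471 for any stage in cultivated corms, 26060 and 20734 in wild corms, 25236 and 5490 for origin over stages, 26483 and 8082 for origin by stage, and 21469 and 3214 for origin by maturity against initial. For genes near 0 in one origin the real counts were 36 and 21, and 1 of 100 splits, the real one, gave as many. The highest other split gave 0, but none of these genes can meet the definition when libraries of both origins are mixed, so this count of splits says nothing about chance.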

How the results depend on the processing

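The removal of the 10 highest genes was chosen after the data were seen; the other alternatives were planned. The direction and side of the threshold of the named genes held in all 221 values computed under the alternatives. These genes were chosen for the largest changes in the same libraries, so this says little about other genes or new samples. Leaving out single libraries gave 600 values, all within 1.5 times the reported count or on the same side. No depth is known, so what depth limits was not assessed. The gene-list alternative (an estimated correlation) was not run because no list was testable. The cause of the changes below was not tested, except where fewer genes were tested by construction.

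With a mean TPM of at least 5, which tests fewer genes, calls were 14316 for cultivated middle versus initial, 14538 for maturity versus initial and 15863 for any stage. In wild corms they were 11630, 14382, 13855 and 14879 (successive steps, then maturity versus initial) and 15989 for any stage. Between origins they were 14379, 14891 and 15008 at initial, middle and late, 15384 over stages, and 16022 and 13614 for the interactions. The 2-fold counts were 6688, 2247 and 7533 in cultivated corms (middle versus initial, late versus middle, maturity versus initial), 1772, 5741 and 8726 in wild corms, 7104, 9421 and 9581 between origins at initial, middle and late, and 7151 for the interaction. With a pseudocount of 0.1 the 2-fold counts rose to 6088 for cultivated late versus middle, 6106 for cultivated maturity versus late and 4281 for wild middle versus initial.

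Scaling lowered the 2-fold count of cultivated maturity versus late to 2017. It turned the share of calls that were higher to 44.1% for cultivated late versus middle (70.9% before), 54.0% for cultivated maturity versus late (15.9% before), 47.0, 43.3 and 45.3% for cultivated against wild at initial, late and maturity, and 42.7% over stages (50.5% before). Without the 10 highest genes the share over stages was 49.2%, and with no filter on low values 49.0%, so this split has no stable direction. Removing these 10 genes also raised the share for cultivated maturity to 33.9% versus late (15.9% before) and 34.4% versus initial (24.1% before). For wild maturity it rose to 40.1% versus late (22.4% before) and 27.9% versus initial (12.9% before).

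The Pearson correlation of the changes in both origins was 0.535 with a pseudocount of 0.1, 0.513 with no filter, 0.539 at a mean TPM of at least 5 and 0.511 after scaling. With the 100 highest genes in place of the 10 highest, the origin difference in TPM share was 2.09 percentage points (permutation p = 0.313). The difference in detected genes was -2072 at a TPM of at least 0.1 (permutation p = 2e-05) and 624 at 5 (permutation p = 0.206). Genes near 0 in one origin numbered 59 and 49 with limits of 0.5 and 2 TPM. Without centring the best matches were 0.772 (cultivated initial with wild middle) and 0.762 (cultivated middle with wild maturity).

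Replicate numbers did not pair the samples: correlations of deviations between libraries with the same number ranged from -0.0875 to 0.168, and 0 libraries matched best their own number in every other group. With the number as a replicate block, the calls were 22697 for cultivated middle versus initial and 23096 for cultivated maturity versus initial, and all 57 values kept their side or lay within 1.5 times the reported count.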

Other observations

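All tests in this part were planned before their results were seen, except the cross-count of peak stages and the order of the cultivated groups, which are descriptions, and the exchange of stage labels, which was tried after the results were seen.

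Genes that peaked at cultivated middle and wild late numbered 1059, against 448 for independent lists, and genes that peaked at cultivated late and wild maturity 856, against 498. Genes that peaked at the initial stage in both numbered 5972, against 4485, and those that peaked at maturity in both 245, against 106. Excesses also lay in the other direction, with cultivated maturity and wild late at 437, against 232, and cultivated late and wild middle at 3411, against 2952. Genes that peaked at middle in both numbered 1014, against 1209, and at late in both 1047, against 1095. A 2-fold rise in cultivated corms with a 2-fold fall in wild corms from initial to maturity was seen in 350 genes, and the reverse in 153. After scaling these numbers were 208 and 297, so their order depends on the scaling. The peak-stage counts are from TPM as deposited.

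Some measures of the cultivated groups run in the order initial, late, middle, maturity and others in the order of the labels. The median TPM was 8.24, 6.46, 4.91 and 4.42 in the first order, and the share of novel1867 0.136, 1.17, 3.66 and 13.2%. Both are taken from a fixed total, so they are not independent measures. After median-of-ratios scaling the median log2 change was -0.11, -0.01 and 0 in the successive steps of the label order. On the second principal component the initial libraries lay at 110 to 122, the late at 39.2 to 39.9, the middle at 12.2 to 14.5 and the mature at -13.1 to -10.6. In the order of the labels EdulChr37G00143200 stood at 96.1, 490, 1397 and 5456 TPM, EdulChr2G00006240 at 331, 2287, 4071 and 21143 TPM, and EdulChr27G00110080 at 3532, 7.14, 0.91 and 0.103 TPM. EdulChr3G00014480 stood at 14.6, 3063, 3235 and 27671 TPM. Among the named genes only novel1867 ran in the first order and not in that of the labels. Of 25386 genes that differed between stages, 3021 had means that only rose or only fell in the order of the labels and 4868 in the other order, and after scaling 3449 and 3590. A course that is not monotone in stage and exchanged middle and late labels could both give this order, and the ratio of 3.54 (3.545 before rounding) with the labels exchanged does not separate them. If the labels were exchanged, each printed change from middle to late in cultivated corms would take the opposite sign, the fall of novel1867 included.

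Cultivated initial replicate 3 stood somewhat apart from the other initial libraries. Its 10 highest genes held 18.7% of TPM, against 14.2 and 13.8% in the other libraries of that group, and IDs without the EdulChr prefix held 14.9%, against 10.4 and 10.3%.

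It was asked whether genes with neighbouring ID serial numbers differ between origins together. Across 19083 pairs of adjacent IDs of one prefix the origin difference over stages correlated at 0.107, above all of 100 shuffles of gene order (-0.0151 to 0.0215). Neighbours may therefore share a small part of their origin difference, which could come from shared regulation, related copies or segments that differ between the plants, none of which was tested apart. Genes are not independent replicates here.

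A related question was whether the genes near 0 in one origin lie next to each other. The 27 such genes with the prefix formed 0 pairs with serial numbers within 100, against a mean of 0.22 in 10000 random draws. The bound set for this test, a number no higher than the random mean, was met but says little, since 80.2% of random draws also held no pair. Whether neighbouring genes are absent together cannot be told apart from the reverse with so few genes.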
